A study of Mus musculus with 5 samples.

How the data were processed

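RNA sequencing measured the transcriptome of CD8+ T cells sorted from mouse tumors. Per the labels, CD8+ T cells of OT-I mice, whose transgenic T cell receptor recognises an ovalbumin peptide, were activated in culture and transferred into mice carrying B16-OVA tumors, a melanoma line that makes ovalbumin. Tumor suspensions from several mice of 1 treatment group were pooled, enriched for CD8+ cells and sorted as live CD8+ CD45.1+ cells. Antibodies against PD-1 and Tim-3 were in the stain, and the labels do not give them as gates. RNA of 5000 to 30000 sorted cells was selected for poly(A), amplified by a modified Smart-seq2 protocol with 8 pre-amplification cycles, and made into libraries by tagmentation and 12 PCR cycles. This chemistry marks neither strand nor molecule, so reads of a gene and an overlapping or antisense gene are not told apart, and PCR copies are counted as separate reads. A floor of 3 counts or an interval from counts therefore covers counting error only.

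The values are whole-number read counts per gene symbol as deposited by the authors, not normalized. TopHat and HTSeq are named with the mouse build mm10, per the submitters' processing notes. Versions, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Each of the 5 libraries lists 23337 genes and 5 counter lines. Those lines were left out of library sizes and tests. Reads without a feature made up 9.02%, 14.0% and 11.2% of the counts of Control IgG replicates 1, 2 and 3, and 7.46% and 15.2% of those of anti-PD-L1 replicates 1 and 2. Ambiguous reads made up 1.38% to 1.51%. Counts assigned to genes numbered 12395682, 9985943 and 12318948 in the Control IgG libraries and 11580960 and 12830485 in the anti-PD-L1 libraries. Levels are given as CPM, a gene's count scaled to a common library total. At these depths a floor of 3 counts lies between 0.234 and 0.300 CPM.

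Groups and replicate numbers were taken from the labels. The labels say that cells of several mice were pooled per library and do not say which mice or days went into which library, so p-values measure the spread between these pools. No 2 libraries were copies of each other, since the chi-square statistic per degree of freedom over genes with at least 10 counts in a pair of libraries ran from 19.2 to 92.3. Coordinates come from GENCODE vM21 on GRCm38, the assembly that mm10 denotes, and 20953 of the 23337 symbols matched it.

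Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test, two-sided, with TMM normalization and the default filterByExpr settings (a minimum count of 10 and a minimum total of 15), which kept 11299 genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of its F statistic. Fold changes are anti-PD-L1 relative to Control IgG, and CPM values of named genes are scaled by the TMM factors, except those of markers of other cell types, which like the sums over lists are divided by library totals only. Log2 CPM values used a prior count of 2. The median standard error over tested genes was 0.38 on the log2 scale, and the biological coefficient of variation was 41.1%.

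The tests, the gene lists and the rule for named genes were fixed before the data were examined. Of the genes past the threshold, the 10 with the largest rise and the 10 with the largest fall would have been named, given a mean log2 CPM of at least 3 and no overlap between groups. Fewer than 5 genes passed in each direction, so the 5 of smallest p per direction under the same terms are named. For each list, the 2 tested members of smallest p are named, or up to 4 past the threshold. Always named are Pdcd1, Havcr2, Lag3, Cd274, Tox, Tcf7, Ifng, Gzmb, Cd8a and Mki67, and for markers of other cell types the 2 members of highest mean CPM. Predicted gene models were passed over. The values of 2 genes that this rule names are not reported here. Gzma, Gzmd, Gzmf, Gzmg and Fn1, which fall outside this rule, and the members of 3 lists in the closing section were chosen after their values were seen.

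The 23 gene lists were tested with camera, two-sided, at a preset inter-gene correlation of 0.01, adjusted over the 23 lists. Marker lists of 10 other cell types were tested in the same way and adjusted apart, where at least 5 members were tested. Of all list symbols, 5 were not matched to a listed gene, older symbols included. Lists were also tested with an estimated correlation and with fry, in limma 3.58.1.

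Counts for the 11299 genes were simulated from the measured means, library sizes and dispersions, with 200 genes changed. The changed genes were picked among those with higher mean counts, so recovery of low genes was not measured. The edgeR test called 8.96% of 67 genes changed 2-fold, 58.2% of 67 changed 4-fold and 86.4% of 66 changed 8-fold. It also called 6 unchanged genes. In the same simulation DESeq2 1.42.0 called 19.4%, 80.6% and 90.9%, along with 34 unchanged genes. A simulated list shifted 1.5-fold had a camera p of 0.00201, and 1 of 100 unshifted lists had a p under 0.05. The simulated genes were drawn independently of each other, without the structure that the libraries numbered 1 share. The shares called therefore need not hold for the measured libraries. Nor does the simulation show that camera holds its error rate on correlated genes.

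Alternatives fixed before the data were examined were DESeq2 size factors, total counts, no low-count filter, a filter of at least 5 CPM in 2 libraries, DESeq2, limma-voom, robust dispersions, the replicate number as a block, each library left out in turn, an adjusted p under 0.1, and a fold of at least 1.5. The DESeq2 alternative used all 15088 genes with a count, so it changed the test, the size factors and the filter together. A fit that leaves a single anti-PD-L1 library takes its spread from the controls alone. A p-value or passing list from such a fit does not measure variation between treated pools. Added after the data were seen were DESeq2 on the 11299 genes, a fit without the 2 libraries numbered 1 and a fit with a term for those libraries. Figures were drawn with matplotlib 3.10.9.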

Results

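The transcriptomes of tumor-infiltrating OT-I CD8+ T cells were compared between mice given an antibody that blocks PD-L1, the ligand of the inhibitory receptor PD-1, and mice given control rat IgG. The cells had been activated in culture and were transferred into mice with a B16-OVA melanoma. Antibody was injected at 200 µg per mouse on days 3 and 6 after transfer, and cells were recovered on day 8 or when a tumor reached 1.2 cm. The series held 3 Control IgG and 2 anti-PD-L1 libraries, with 9985943 to 12830485 counts assigned to genes. Control IgG replicate 1 and anti-PD-L1 replicate 1 had 11696 and 11977 genes with at least 1 count, against 13564 to 13801 in the other 3 libraries. After thinning every library to 9985943 counts these 2 still had 11439 and 11723, against 13167 to 13335. Log2 CPM values correlated across genes at 0.973 to 0.977 among those other 3 libraries and at 0.907 to 0.936 in every pair that held a library numbered 1, where genes are not independent replicates. The first principal component, with 52.7% of the variance, separated the libraries numbered 1 from the rest, and the second, with 34.5%, set them apart from each other.

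The main comparison asked which genes differ in tumor-infiltrating T cells after PD-L1 blockade. The genes with the strongest evidence of a higher level after anti-PD-L1 encoded granzymes, the serine proteases of cytotoxic granules, and serpins, which inhibit serine proteases. Granzyme E (Gzme) had a log2 fold change of 3.19 ± 0.61 (SE), from 2.90 ± 0.888 CPM (SD, n = 3) to 26.6 ± 22.7 CPM (SD, n = 2). Granzyme C (Gzmc) had 2.62 ± 0.62, Serpinb9b 2.67 ± 0.60, Serpine2 1.73 ± 0.35, and Gng11, a G protein gamma subunit, 2.20 ± 0.53. The genes with the strongest evidence of a lower level were Bzw2 at -1.02 ± 0.29, the spermidine synthase Srm at -1.08 ± 0.33, the zinc finger gene Zfp426 at -1.36 ± 0.41, the nucleolar protein nucleolin (Ncl) at -0.87 ± 0.28 and the mitochondrial prolyl-tRNA synthetase Pars2 at -1.33 ± 0.43. Both anti-PD-L1 libraries lay outside the range of the 3 Control IgG libraries for each of these 10 genes, which is part of the rule by which they were named.

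None of the 11299 tested genes passed an adjusted p of 0.05 in either direction in edgeR's quasi-likelihood test, in which the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 134 genes higher and 107 lower, 241 in all, where chance alone would give about 565. DESeq2, run on all 15088 genes with a count and with its own size factors and filtering, called 4 genes higher and 0 lower, namely Gzme, Serpinb9b, Gzmc and Serpine2, at DESeq2 adjusted p-values of 0.00803 to 0.0188. It called the same 4 on the 11299 genes, at 0.00867 to 0.0106, and edgeR on the 15088 genes, without a low-count filter, called these 4 and Gzmf. In limma-voom 0 genes passed. Without both libraries numbered 1, edgeR called 1 gene, Gzma, at an adjusted p of 0.004. That fit sets a single anti-PD-L1 library, with 8792 Gzma counts, against 2 controls with 2209 and 1457. Its spread comes from these controls alone. The libraries left out had 6817 Gzma counts in the control and 11272 after anti-PD-L1. Among 8281 genes with a mean log2 CPM of at least 3, both anti-PD-L1 libraries lay above all Control IgG libraries for 7.11% and below them for 10.0%, where chance gives 10% each.

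Of the 10 leading genes, Gzme and Gzmc lie in the same gene cluster as Gzmb. On GRCm38, Gzme spans chromosome 14 from 56117626 to 56120625, Gzmc from 56231441 to 56234656 and Gzmb from 56258838 to 56262260, all on the minus strand. Serpinb9b lies on chromosome 13 from 33027416 to 33041884, and Serpine2 on chromosome 1 from 79794197 to 79861180. Nucleolin is also on chromosome 1, from 86344719 to 86359400, and Srm is on chromosome 4 from 148591503 to 148594993.

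**Figure D1:**
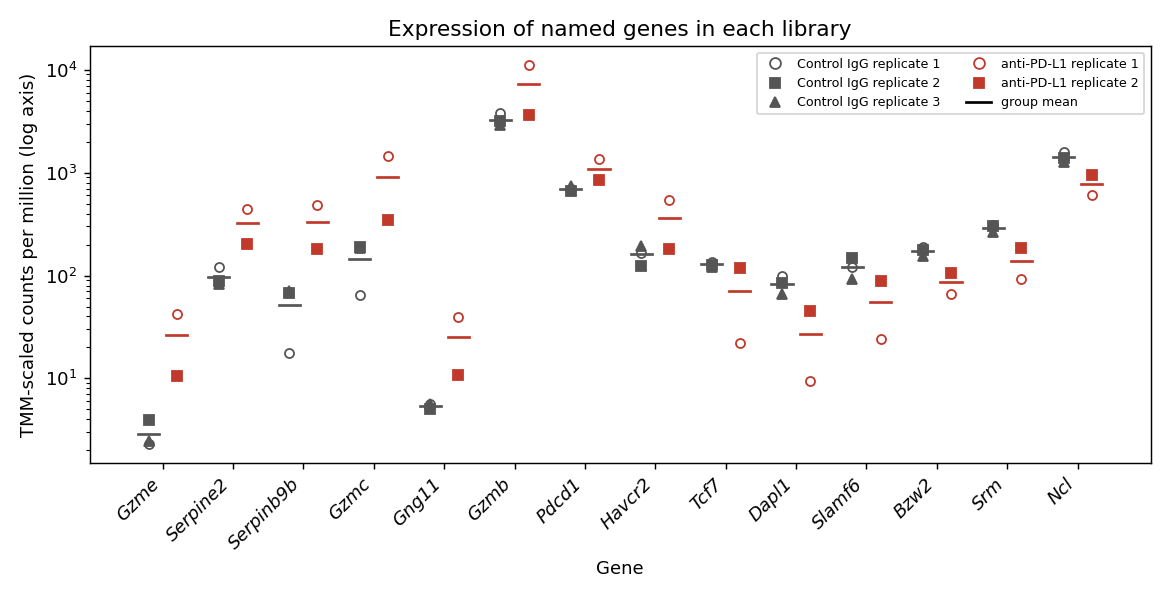
TMM-scaled CPM on a log axis for 14 named genes (Gzme, Serpine2, Serpinb9b, Gzmc, Gng11, Gzmb, Pdcd1, Havcr2, Tcf7, Dapl1, Slamf6, Bzw2, Srm and Ncl), with 1 point per library, Control IgG in grey, anti-PD-L1 in red, open circles for the libraries numbered 1 and bars for group means. Anti-PD-L1 replicate 1 is farther from the Control IgG libraries than replicate 2 for each gene drawn, as for Gzme at 42.7 against 10.6 and Tcf7 at 22.3 against 119.

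Of the 20 tested cytotoxic effector genes, 19 had a fold change above 0, and both anti-PD-L1 libraries lay above every control for 9, where chance gives 10%. The list median was 0.59. Gzmb, the major granzyme of activated CD8+ T cells, stood at 3285 ± 458 CPM (SD, n = 3) in controls and 7332 ± 5283 CPM (SD, n = 2) after anti-PD-L1, a log2 fold change of 1.16 ± 0.42. The rise came from anti-PD-L1 replicate 1, at 11070 CPM, since replicate 2, at 3596 CPM, lay within the controls at 2909 to 3795 CPM. No member passed over all genes. Adjusted over the list alone, 5 passed, namely Gzmc, Gzmd, Gzme, Gzmf and Gzmg, at edgeR adjusted p-values of 0.0146 to 0.0198. This adjustment covers the 20 members only and takes no account of the other lists examined in the same way. Gzmg had 0 counts in every control and 25 and 32 counts after anti-PD-L1, at least 8.88-fold higher against a floor of 3 counts per library, and the list median was 0.59 also with Gzmg at this bound. These 5 genes are close paralogs, and reads shared between them make their separate values uncertain. The whole list of 20 stood above the other genes in camera at an adjusted p of 1.45e-16, and at an adjusted p = 0.301 with an estimated correlation. The median member was 0.95 above the control mean in anti-PD-L1 replicate 1 and 0.23 above it in replicate 2, while Control IgG replicate 1, the other library with fewer detected genes, was 0.29 above it. The list median was 0.21 without anti-PD-L1 replicate 1 and 0.96 without replicate 2. Natural killer markers, treated below, rose in the same library, with a median of 1.27 in anti-PD-L1 replicate 1 and 0.02 in replicate 2.

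Inhibitory receptors restrain T cell activity and mark exhausted cells. The list of them, which also held the ligand genes Cd274 and Pdcd1lg2 and the enzyme genes Cd38 and Entpd1, leaned the same way. Of 15 tested, 12 had a fold change above 0, with a list median of 0.44. Pdcd1, which encodes PD-1, had a log2 fold change of 0.65 ± 0.27, from 697 ± 39.9 CPM (SD, n = 3) to 1095 ± 360 CPM (SD, n = 2). The fold change was 1.17 ± 0.43 for Havcr2, which encodes Tim-3, 0.44 ± 0.32 for Lag3, 1.47 ± 0.47 for Cd38 and 1.37 ± 0.49 for Entpd1, which encodes the ectonucleotidase CD39. For Havcr2 and Entpd1 the fold came from anti-PD-L1 replicate 1, at 544 and 277 CPM, as replicate 2, at 180 and 76.3 CPM, lay within the controls at 124 to 192 and 56.4 to 91.3 CPM. Lag3 was likewise within the controls in replicate 2. Cd274, which encodes PD-L1 itself, stood at 0.11 ± 0.31. None of the 15 passed over all genes or adjusted over the list alone. The list passed in camera at an adjusted p of 8.24e-04, with an adjusted p = 0.301 with an estimated correlation. Its median member was 0.81 above the control mean in anti-PD-L1 replicate 1 and 0.16 in replicate 2, and without replicate 1 the list had a median of 0.14 and an adjusted p of 0.069. Without replicate 2 the median was 0.82.

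Exhaustion-linked transcription factors had a median of 0.07 over 17 tested members, and 11 lay above 0. The list did not pass in camera, at an adjusted p of 0.163. Prdm1, which encodes Blimp-1, had a log2 fold change of 0.89 ± 0.30, Id2 0.95 ± 0.36 with anti-PD-L1 replicate 2 within the range of the controls, and Tox, a driver of the exhausted state, 0.07 ± 0.30. The median member was 0.36 above the control mean in anti-PD-L1 replicate 2 and lay at -0.22 in replicate 1. Without replicate 1 the list median was 0.35, and without replicate 2 it was -0.19, each from a single anti-PD-L1 library.

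Genes of naive, memory and progenitor T cells were lower after anti-PD-L1 in 17 of 21 cases, with a median of -0.24. Dapl1 had a log2 fold change of -1.61 ± 0.58, Slamf6 -1.11 ± 0.51, and Tcf7, which encodes the progenitor factor TCF-1, -0.85 ± 0.58. No member passed over all genes or adjusted over the list alone. The list passed in camera at an adjusted p of 5.1e-05, with an adjusted p = 0.687 with an estimated correlation. The median member lay at -1.17 in anti-PD-L1 replicate 1 and at 0.21 in replicate 2. Tcf7 stood at 22.3 CPM in anti-PD-L1 replicate 1, at 119 CPM in replicate 2 and at 122 to 136 CPM in the controls, and without replicate 1 the list median was 0.19.

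Effector differentiation genes had a fold change above 0 in 13 of 17 cases, and both anti-PD-L1 libraries lay above every control for 4. Il12rb2, the signalling chain of the interleukin-12 receptor, had 1.43 ± 0.44 and the chemokine receptor Cx3cr1 1.08 ± 0.37. The median was 0.13, the adjusted p in camera was 0.00196, and the adjusted p = 0.301 with an estimated correlation. With 1 library left out, the median ran from 0.067 without anti-PD-L1 replicate 2 to 0.32 without Control IgG replicate 3. The median member was 0.13 above the control mean in anti-PD-L1 replicate 1 and 0.28 in replicate 2. Of the 10 lists past the threshold, only this list and the cytotoxic list stayed past it whichever library was left out. Their medians changed as given. This is weak evidence of a treatment effect, since leaving out either anti-PD-L1 library leaves a single one, whose spread is not measured. Of the 10 splits of the 5 libraries into 3 and 2, 8 passed at least as many lists as the real one, itself included.

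Trafficking and tissue residency genes had a median of 0.23 over 20 tested members, with 13 above 0. The chemokine receptor Ccr2 had a log2 fold change of 1.21 ± 0.34, with both anti-PD-L1 libraries above every control. The list passed in camera at an adjusted p of 0.0286, with an adjusted p = 0.545 with an estimated correlation. Its median member lay at -0.23 in anti-PD-L1 replicate 1 and 0.30 above the control mean in replicate 2. The adjusted p was 0.25 without Control IgG replicate 2, and the median was -0.23 without anti-PD-L1 replicate 2.

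Type I interferon response genes had a fold change above 0 in 30 of 32 cases, with a median of 0.44. Isg20, an interferon-induced exonuclease, had 1.03 ± 0.36 and Usp18, a negative regulator of interferon signalling, 1.13 ± 0.44 with anti-PD-L1 replicate 2 within the range of the controls. The list passed in camera at an adjusted p of 3.61e-08, with an adjusted p = 0.646 with an estimated correlation. Its median member was 0.86 above the control mean in anti-PD-L1 replicate 1 and 0.09 in replicate 2, and lay at -0.23 in Control IgG replicate 1. Without anti-PD-L1 replicate 1 the median was 0.07 and the adjusted p 0.642. Interferon-gamma response genes did not pass with all libraries, at an adjusted p of 0.69, and passed downward without Control IgG replicate 2, at 0.0282 with a median of -0.09. Their median over 27 members was 0.05, while their mean was -0.08 and the test pointed down. Iigp1 had -1.26 ± 0.52 and Tgtp1 -1.15 ± 0.52, both interferon-inducible GTPases, and each was highest in Control IgG replicate 1, at 84.9 and 54.4 CPM.

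Cytokine and chemokine genes went both ways, with 9 above and 10 below 0 of 19 tested, a median of -0.05 and an adjusted p of 0.699 in camera. Ifng, the main cytokine of effector CD8+ T cells, had a log2 fold change of 0.12 ± 0.26. Spp1, which encodes osteopontin, had 1.26 ± 0.41, and Il3 -2.12 ± 0.85, both mainly from anti-PD-L1 replicate 1. Spp1 stood at 1887 CPM there and 679 CPM in replicate 2, against 425 to 651 CPM in the controls. Il3 stood at 0.464 and 4.99 CPM, against 9.21 to 14.95 CPM in the controls.

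T cell receptor complex and signalling genes had a median of 0.07 over 20 members and an adjusted p of 0.266. Cd8a, part of the coreceptor used in the sort, had 0.09 ± 0.29, Cd3g 0.33 ± 0.28 and Cd3d 0.32 ± 0.28. Costimulatory receptors had a median of -0.10 and a mean of -0.02 over 13 members, while the test pointed up, at an adjusted p of 0.902. Tnfrsf1b had 0.66 ± 0.27 and Tnfrsf4, which encodes OX40, -0.32 ± 0.27.

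Activation-induced immediate early genes, which follow receptor stimulation within minutes to hours, moved in opposite directions in the 2 anti-PD-L1 libraries. The median of the 25 members lay at -0.70 in replicate 1 and 0.57 above the control mean in replicate 2. The list median was 0.09 and the mean 0.07, while the test pointed down, at an adjusted p of 0.902. Dusp2 had 0.48 ± 0.29 and Rel 0.56 ± 0.34. Without anti-PD-L1 replicate 1 the list median was 0.57, and without replicate 2 it was -0.78, each from a single anti-PD-L1 library.

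Cell cycle genes also differed between the anti-PD-L1 libraries. G2 and M phase genes had a median of 0.14 over 28 members and an adjusted p of 0.167, with the median member at 0.53 in replicate 1 and at -0.41 in replicate 2. Without replicate 1 their median was -0.41 and without replicate 2 it was 0.53, each from a single anti-PD-L1 library. Bub1 had 0.88 ± 0.44 with anti-PD-L1 replicate 2 within the range of the controls, and Cenpa, the centromeric histone, 0.33 ± 0.24. Mki67, the proliferation marker Ki-67, had -0.48 ± 0.89. It stood at 33.2 and 70.0 CPM in the 2 libraries numbered 1 and at 260 to 408 CPM in the other 3. The median G2 and M phase gene did not share this drop, at -0.096 in Control IgG replicate 1 and 0.53 in anti-PD-L1 replicate 1. S phase genes were lower in 25 of 28 cases, with a median of -0.22, an adjusted p of 0.00543 and an adjusted p = 0.814 with an estimated correlation. Cdc45 had -0.48 ± 0.25 and Ung -0.50 ± 0.30. The median S phase gene lay at 0.05 in anti-PD-L1 replicate 1 and at -0.45 in replicate 2. The adjusted p was 0.266 without Control IgG replicate 1, and the median was 0.07 without anti-PD-L1 replicate 2.

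Cytosolic ribosomal protein genes had a fold change below 0 in 33 of 36 cases, with a median of -0.20, an adjusted p of 0.00224 and an adjusted p = 0.846 with an estimated correlation. Rpl14 had -0.43 ± 0.28 and Rps4x -0.36 ± 0.24. The median member was 0.35 above the control mean in Control IgG replicate 1, and without that library the list median was 0.02. Without anti-PD-L1 replicate 2 the adjusted p was 0.0681. Heat shock and dissociation stress genes had a median of -0.35 over 16 members, with 13 below 0, an adjusted p of 0.0148 and an adjusted p = 0.814 with an estimated correlation. The chaperones Hspd1 and Hsp90aa1 had -0.68 ± 0.30 and -0.57 ± 0.26. The median member lay at -0.59 in anti-PD-L1 replicate 1, at 0.13 in replicate 2 and at 0.37 in Control IgG replicate 1. The list median was 0.05 without anti-PD-L1 replicate 1, and the adjusted p was 0.313 without Control IgG replicate 1.

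Hypoxia response genes had a median of 0.17 over 18 tested members, with 14 above 0, an adjusted p of 0.0148 and an adjusted p = 0.374 with an estimated correlation. Ddit4, an inhibitor of mTORC1, had 0.68 ± 0.35 and Ndrg1 0.47 ± 0.25, and both anti-PD-L1 libraries lay above every control for each. The median member was 0.19 above the control mean in anti-PD-L1 replicate 1 and 0.20 in replicate 2. The list missed the threshold without Control IgG replicate 3, at 0.0993, without anti-PD-L1 replicate 2, at 0.0824, and without both libraries numbered 1, at 0.0508. With 1 library left out, the median ran from 0.16 without anti-PD-L1 replicate 1 to 0.34 without Control IgG replicate 2, and it was 0.058 without both libraries numbered 1.

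Glycolysis genes had a median of 0.14 over 18 members and an adjusted p of 0.056, which fell below 0.05 with DESeq2 size factors, at 0.0499, and without the low-count filter, at 0.0336. The glucose transporter Slc2a3 had 1.53 ± 0.52 and the lactate transporter Slc16a3 0.69 ± 0.35, both with anti-PD-L1 replicate 2 within the range of the controls. Their median member lay at 0.44 in anti-PD-L1 replicate 1 and at -0.16 in replicate 2, and the list passed without Control IgG replicate 1 and without either anti-PD-L1 library, downward where replicate 1 was left out. Cholesterol synthesis genes had a median of 0.24 over 20 members and an adjusted p of 0.302, with the transcription factor gene Srebf2 at 0.44 ± 0.27. Their median member lay at 0.56 in anti-PD-L1 replicate 1 and at -0.25 in replicate 2. The list median was -0.27 without replicate 1 and 0.57 without replicate 2. Oxidative phosphorylation genes had a median of -0.08 over 32 members and an adjusted p of 0.671, with Ndufa4 at -0.37 ± 0.30 and Cyc1 at -0.28 ± 0.23. They passed upward without Control IgG replicate 1, with a median of 0.14, and downward without anti-PD-L1 replicate 1, with a median of -0.29. Fatty acid oxidation genes had a median of -0.09 and a mean of 0.01 over 19 members, while the test pointed up, at an adjusted p of 0.902. Cpt1a, which controls fatty acid entry into mitochondria, had 0.82 ± 0.41 with anti-PD-L1 replicate 2 within the range of the controls, and Slc25a20 0.53 ± 0.28. This list passed only without anti-PD-L1 replicate 1 among the fits that left out 1 library, with a median of -0.21.

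Genes of the unfolded protein and integrated stress response had a median of -0.09 over 20 tested members and an adjusted p of 0.233. Asns, which encodes asparagine synthetase, had -0.81 ± 0.27 with both anti-PD-L1 libraries below every control, and Atf4 had -0.44 ± 0.39. The list passed without Control IgG replicate 3, at an adjusted p of 0.0374. Apoptosis regulators had a median of 0.20 over 21 tested members and an adjusted p of 0.19. Cdkn1a, which encodes the cell cycle inhibitor p21, had 1.07 ± 0.35 and the pro-apoptotic Pmaip1 0.53 ± 0.32. They passed without Control IgG replicate 1, at 0.0116. Over all 23 lists, 10 passed in camera with the preset correlation, 6 upward and 4 downward. With an estimated correlation 0 passed, and with fry, which tests whether the genes of a list move one way on balance, 0 passed, with a smallest adjusted p of 0.64. Without both libraries numbered 1, 11 lists passed, 5 of them among these 10.

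**Figure D2:**
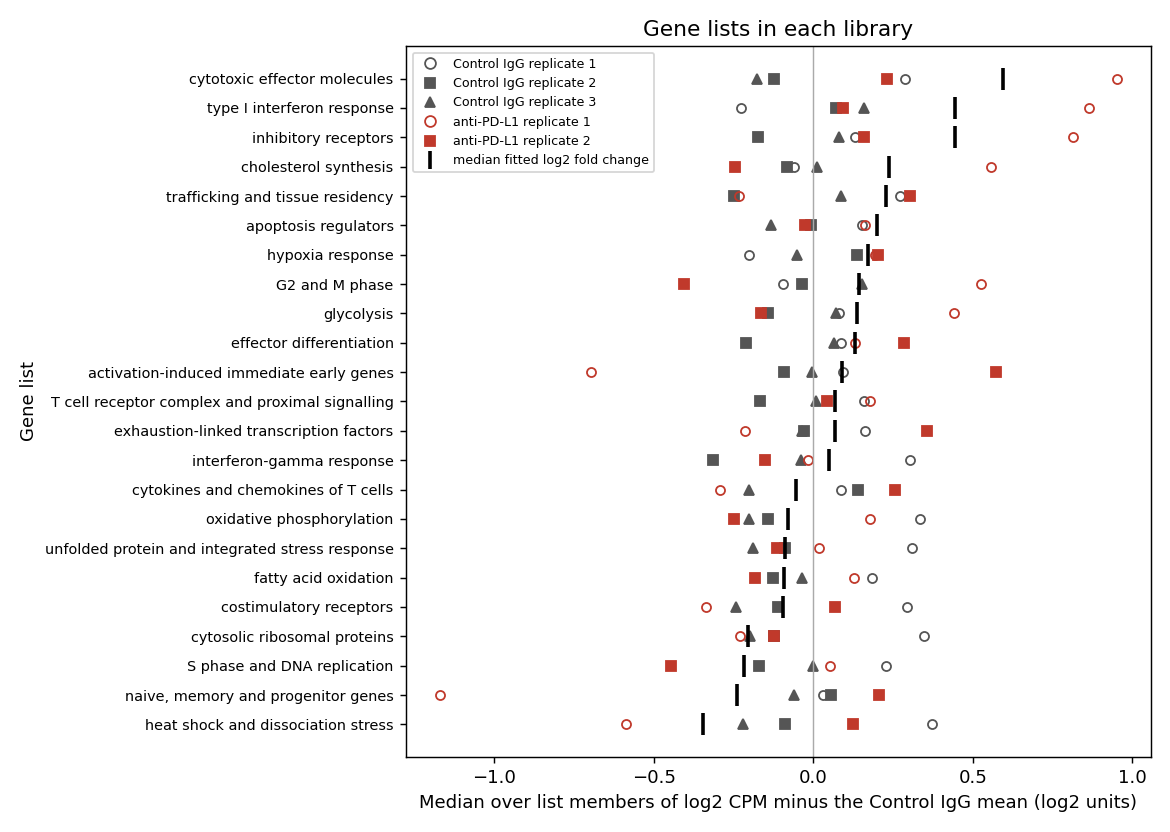
Median over the members of each of the 23 gene lists of log2 CPM minus the Control IgG mean, in log2 units, with 1 point per library, Control IgG in grey, anti-PD-L1 in red, open circles for the libraries numbered 1, and a black bar for the median fitted log2 fold change. Anti-PD-L1 replicate 1 lies farthest out for many lists, from -1.17 for progenitor genes to 0.95 for cytotoxic genes.

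Transcripts typical of other cells were present at levels that varied between libraries. Summed over the melanoma list, they reached 9.92, 421 and 133 CPM in Control IgG replicates 1, 2 and 3 and 54.5 and 145 CPM in anti-PD-L1 replicates 1 and 2. Pmel and Dct led this list, at 1.29 and 0.484 CPM in Control IgG replicate 1 and 112 and 80.7 CPM in Control IgG replicate 2. Macrophage genes summed to 273 to 485 CPM, most of it from Ctss and Lyz2, and dendritic cell genes to 147 to 435 CPM, led by Cd74 and H2-Ab1. Ctss, Cd74 and H2-Ab1 are also expressed by T cells or interferon-treated cells to some degree. Neutrophil genes, with Cxcr2 and Ltf the highest, summed to 14.0 to 18.1 CPM. The CD4 and regulatory T cell list summed to 294 to 568 CPM, led by Ctla4 and Gata3, which activated CD8+ T cells also express. These 5 lists did not pass in camera, at adjusted p-values of 0.455 to 0.684. With 1 library left out, the melanoma list passed downward without Control IgG replicate 1, at 9.17e-07, and upward without Control IgG replicate 2, at 0.0194. The macrophage list passed downward without Control IgG replicate 3, at 0.00934, and the CD4 list upward without anti-PD-L1 replicate 1, at 0.0331.

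The natural killer list passed upward at an adjusted p of 0.0209, with an adjusted p = 0.786 with an estimated correlation. It was led by Klre1 and Klri2, lectin-like receptors that activated CD8+ T cells can share, at 202 and 70.1 CPM in anti-PD-L1 replicate 1, against 56.0 to 93.8 and 33.9 to 43.2 CPM in the other libraries. The median member was 1.27 above the control mean in anti-PD-L1 replicate 1 and 0.02 in replicate 2. The adjusted p was 0.967, pointing down, without anti-PD-L1 replicate 1 and 0.0848 without Control IgG replicate 2. For 4 lists only 2 members each were tested, too few for the list test. B cell genes summed to 10.4 to 29.3 CPM, with Sdc1 and Cd79b the highest. Endothelial genes summed to 29.4 to 63.6 CPM, led by Pecam1 and Egfl7, and erythroid genes to 0.701 to 21.6 CPM, led by the beta-globin gene Beta-s and by Alas2. Fibroblast genes summed to 235 to 376 CPM, nearly all from Thy1, which T cells express, while Sparc was seen only in Control IgG replicate 2, at 3.71 CPM. Adjusted over the list alone, 1 fibroblast gene, Fn1, passed in edgeR, at 0.0495. This adjustment too takes no account of the other lists. Fn1 had 7, 9 and 12 counts in the controls and 0 in both anti-PD-L1 libraries. That is at least 3.30-fold lower against a floor of 3 counts per library.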

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

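The fits without the 2 libraries numbered 1, with a term for them, and with DESeq2 on the filtered genes, were chosen after the data were seen. The count of genes lower after anti-PD-L1 was 0 in every setting tried. The count higher was 0 except without a low-count filter (5), with DESeq2 on all genes with a count (4), with DESeq2 on the filtered genes (4) and with both libraries numbered 1 left out (1, Gzma, adjusted p 0.004, from a single anti-PD-L1 library and the spread of 2 controls, the control left out having 6817 counts against 2209 and 1457). The anti-PD-L1 library left out of that last fit had 11272 Gzma counts, against 8792 in the one kept. Without the filter 15088 genes are tested in place of 11299. In edgeR dropping the filter alone added the 5 genes, while DESeq2 called the same 4 on either set. The cause of the other differences was not tested. The smallest adjusted p ran from 0.004 to 0.99997 over the settings. The 10 lists past the threshold became 0 with an estimated correlation and 0 with fry, and 10 to 13 in the other settings. Of the 10, 7 remained without Control IgG replicate 1, 6 without either anti-PD-L1 library and 5 without both libraries numbered 1. Of the 64 genes taken by the naming rule, markers of other cells aside, 54 kept their sign in every setting. Apart from the genes always named, the rule picks by separation or small p on these same libraries, which favours a stable sign. Of the 23 list medians 4 kept their sign, those of inhibitory receptors, cytotoxic effector molecules, effector differentiation and hypoxia.

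Only 2 replicate numbers are shared and the labels tie them to no day or animal. Deviations from the group means correlated at 0.37 and 0.45 for equal numbers and, as 2 libraries of a group deviate oppositely by construction, at -0.37 and -0.45 for unequal ones. With the number as a block, 0 genes passed in either direction and 12 lists did, 9 of them among the 10. Hypoxia (adjusted p 0.093) was not among the 12, and glycolysis (0.0487), oxidative phosphorylation (0.0487) and the unfolded protein response (0.0241) were added. Log2 fold changes that reversed with the block were those of Cd8a (-0.00056), Ifng (-0.022) and Mki67 (0.21), and among list medians immediate early genes (-0.046). The smallest adjusted p with the block was 0.819.

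With both libraries numbered 1 left out, the fold changes of Bub1 (-0.28), Tox (-0.024) and Usp18 (-0.071) reversed, as did the medians of cytokines (0.26), costimulatory receptors (0.26), type I interferon (-0.0027), interferon-gamma (-0.045), G2 and M phase (-0.45), glycolysis (-0.15), cholesterol synthesis (-0.22), heat shock (0.16) and cytosolic ribosomal proteins (0.048). With a term for these libraries, Mki67 (0.27), Tox (-0.019), cytokines (0.010) and interferon-gamma (-0.0072) reversed. Cytokines also reversed without a low-count filter (0.013) and with the stricter filter (0.032). The cause was not tested.

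Each library left out in turn, with a lone anti-PD-L1 library assumed to vary like the controls, reversed some values, which then ranged from -0.13 to 1.5 for Bub1, -0.25 to 0.42 for Cd274, -0.037 to 0.66 for Cd3g, -0.16 to 0.34 for Cd8a, -0.020 to 0.24 for Ifng, -0.012 to 0.82 for Lag3, -1.71 to 0.19 for Mki67, -0.10 to 1.03 for Rel and -0.21 to 0.33 for Tox. List medians ranged from -0.19 to 0.35 for exhaustion-linked factors, -0.28 to 0.19 for cytokines, -1.22 to 0.19 for progenitor genes, -0.31 to 0.084 for costimulatory receptors, -0.016 to 0.18 for the T cell receptor complex, -0.78 to 0.57 for immediate early genes, -0.19 to 0.12 for interferon-gamma, -0.41 to 0.53 for G2 and M phase, -0.46 to 0.067 for S phase, -0.19 to 0.46 for glycolysis, -0.29 to 0.19 for oxidative phosphorylation, -0.21 to 0.092 for fatty acid oxidation, -0.27 to 0.57 for cholesterol synthesis, -0.15 to 0.077 for the unfolded protein response, -0.71 to 0.051 for heat shock, -0.23 to 0.31 for trafficking, -0.070 to 0.31 for apoptosis and -0.30 to 0.018 for cytosolic ribosomal proteins. Without anti-PD-L1 replicate 2 the count at an unadjusted p under 0.05 went from 134 to 476 higher and from 107 to 651 lower, with 0 past the threshold, and without replicate 1 it went to 43 and 20. Depth limits the low genes, such as Gzmg and Fn1, which were at 0 counts in a whole group.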

Other observations

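The 2 lists in the next paragraph, the further ribosome biogenesis genes, the tests of sequencing depth, the libraries numbered 1 and S phase were chosen after the results were seen, while the tests of shared zeros, transcript length, natural killer cells and other splits were set out before their results.

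Genes of ribosome biogenesis and linked growth functions, a list of 30 put together after the data were seen, had a log2 fold change below 0 in 30 of 30 cases, with a median of -0.69. Both anti-PD-L1 libraries lay below every control for 22 of them, where chance gives 10%. Nucleolin (Ncl) had -0.87 ± 0.28, nucleophosmin (Npm1) -0.84 ± 0.31, fibrillarin (Fbl) -0.70 ± 0.29 and the snoRNP protein Nop58 -0.78 ± 0.32. The camera test gave an adjusted p of 3.47e-25, and an adjusted p = 0.0994 with an estimated correlation. In the opposite direction, 17 of 17 tested genes of the S100, annexin and galectin families were above 0, with a median of 0.63, a camera adjusted p of 4.14e-13 and an adjusted p = 0.103 with an estimated correlation. Most of this rise was in anti-PD-L1 replicate 1, where the median member was 1.01 above the control mean, against 0.19 in replicate 2 and 0.12 in Control IgG replicate 1. For ribosome biogenesis genes the medians were -0.96 and -0.36 in anti-PD-L1 replicates 1 and 2. Lgals3 had 1.38 ± 0.34, S100a4 1.16 ± 0.36, Anxa1 1.13 ± 0.36 and Lgals1 0.90 ± 0.35. None of these genes passed over all genes in edgeR, and a list picked for its values on these libraries is no independent evidence of its direction.

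The 2 anti-PD-L1 pools lay apart in several gene groups. Against Control IgG replicate 1, anti-PD-L1 replicate 1 had medians of 1.25 for type I interferon genes, 0.65 for G2 and M phase, -0.93 for immediate early genes and -1.21 for progenitor genes. Against Control IgG replicates 2 and 3, anti-PD-L1 replicate 2 had 0.02, -0.42, 0.66 and -0.06 for the same lists, with all 25 immediate early genes above 0. Cytotoxic genes were above 0 in 14 of 20 cases in the first comparison and 20 of 20 in the second. These are differences between single anti-PD-L1 libraries and the controls, with no replicate check.

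Other splits of the 5 libraries into 3 and 2 number 10 with the real one, too few for a share under 0.05. The real split gave 241 genes at an unadjusted p under 0.05, 5 of the 10 splits gave as many, and the highest other gave 2588. That split set the 2 libraries numbered 1 against the rest, had 105 genes past an adjusted p of 0.05 in edgeR, and points to a structure of the samples that crosses the treatment. With a term for it, 0 genes passed for treatment in either direction. Of the fixed lists, 10 passed in the real split, 8 of the 10 splits gave as many, and the highest other gave 15.

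The 2 libraries numbered 1 detected fewer genes than the other 3. Sequencing depth is argued against, since a gap of 1444 genes to the nearest other library was left after thinning. A lack of transcripts from other cells would put the same genes at 0 in both, and among 11221 genes with at least 5 counts in each of the other 3 libraries, 471 and 343 were at 0 and 151 in both, an odds ratio at matched abundance of 3.39 (95% interval 2.63 to 4.37), below the 5 set in advance for this as the whole cause, though above 1. Transcripts of other cells moved apart, as melanoma transcripts were lowest in these 2, at 9.92 and 54.5 CPM, while macrophage and dendritic cell transcripts were highest in Control IgG replicate 1, at 485 and 435 CPM, against 273 and 147 CPM in anti-PD-L1 replicate 1. Loss of long transcripts stays open. Long genes were at 0 more often in anti-PD-L1 replicate 1, with an odds ratio of 1.55 (1.21 to 1.98), and by 1.20 (0.968 to 1.5) in Control IgG replicate 1. Over genes longer than 8000 bases the median level was -0.50 and -0.57 in these libraries relative to the other 3. The level also fell with transcript length, at Spearman correlations of -0.229 in anti-PD-L1 replicate 1 and -0.375 in Control IgG replicate 1. In the other 3 libraries these were -0.0501 to 0.118. Reads without a feature were also lowest in these 2, at 9.02% in Control IgG replicate 1 and 7.46% in anti-PD-L1 replicate 1, against 11.2% to 15.2% in the other 3. No other explanation, biological or technical, was tested, as the labels give nothing that sets these 2 apart. Sorted cells are given only as a range of 5000 to 30000 for every library.

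Cytotoxic genes were higher and progenitor genes lower mainly in anti-PD-L1 replicate 1. Natural killer cells, which the CD8 and CD45.1 gate should remove, are argued against as the whole cause by Ncr1 and Klrb1c, which summed to 2.94 CPM there and up to 5.11 CPM in a control, with 0 and 34 counts. The natural killer list as a whole did pass upward, at 0.0209, with a median of 1.27 in that library, led by receptors that CD8+ T cells can share. CD3 and CD8 genes had a median of 0.34 above the control mean there and 0.27 in Control IgG replicate 1. The structure shared by the libraries numbered 1 was fitted as a term, and a shift remained in both lists. Cytotoxic genes kept a median of 0.512 (95% interval over members 0.21 to 1.52) and a camera adjusted p of 1.89e-12 at a preset correlation. Progenitor genes kept -0.314 (-1.12 to -0.0709) and 2.08e-04. With an estimated correlation the camera adjusted p was 0.338 and 0.721. These intervals take list members as separate and do not measure the spread between pools. The fit therefore cannot exclude this structure as the cause. Anti-PD-L1 replicate 2, against Control IgG replicates 2 and 3, had a cytotoxic median of 0.418 and a progenitor median of -0.0553. There 0 cytotoxic genes and 11 of 21 progenitor genes were below 0. Against Control IgG replicate 1 alone, the cytotoxic median in anti-PD-L1 replicate 1 was 0.62, with an interval from -0.139 to 1.87. A response to treatment and a difference in the state of the pooled tumors may each give this pattern, and with the progenitor shift of -1.21 absent from anti-PD-L1 replicate 2 they are open hypotheses.

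Ribosome biogenesis genes were lower in both anti-PD-L1 libraries. Since the list was picked on these libraries, the structure of those numbered 1 was tested on 77 further ribosome biogenesis genes chosen by function. With a term for these libraries the further genes kept a median of -0.395 (95% interval over members -0.453 to -0.31), with 74 below 0. The camera adjusted p was 2.99e-17 at a preset correlation and 0.141 with an estimated one. The further genes share a function with the list and were read on the same libraries, so they are no independent check. The interval covers members and not pools. The shift remained with the term, but this cannot exclude the structure as the cause. Fewer cells in S phase are argued against as the whole cause in anti-PD-L1 replicate 1, where the S phase list had a median of 0.051 against all controls. Against Control IgG replicate 1 alone that median was -0.184, with 20 of 28 genes below 0, beside -1.18 for ribosome biogenesis. A smaller part from S phase is left open there. Fewer cells in S phase remain a candidate explanation in replicate 2, where the S phase list had -0.45 beside -0.36 for ribosome biogenesis. Lower growth signalling after blockade is a hypothesis only, since the list was found on these same libraries and its estimated-correlation p missed the threshold.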
